A study of Mus musculus with 2 samples.

How the data were processed

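Trimethylation of lysine 27 on histone H3 (H3K27me3), the mark deposited by Polycomb repressive complex 2 on silenced genes, was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in whole kidney from mouse embryos at embryonic day 16.5. Per the labels, the strain was B6NCrl, each sample was a pool of male and female embryos, and the 2 samples were biological replicates of 1 group, each made from a pair of technical replicates. The pool of replicate 2 held 41 embryos per the labels, and the number in replicate 1 was not given in the sources used here. No control samples were among the files analysed here, and there was no second condition, so the comparisons were between the replicates, between gene groups and between chromosomes within this tissue.

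The authors deposited 4 peak lists in narrowPeak format on build mm10, per the labels and the deposited text files that describe the lists. There was 1 list for each replicate, a joint list made from both replicates together, and a replicated list derived from the other lists. The peak caller, its version, its thresholds and the rule for keeping a replicated peak were not given in the sources used here. In the deposited lists each peak carries the authors' score, which is a display value, and this score was not used. The signal of each peak is the authors' own value within its list. The −log10 p and −log10 q of each peak are the authors' values, and were used only to rank and filter peaks within a list. The smallest −log10 p in the replicate lists was 2.01 in replicate 1 and 2.04 in replicate 2. The smallest −log10 q was 0.242 and 0.401, and the median 1.97 and 2.78. A −log10 q of at least 2 was reached by 32286 of 68859 peaks in replicate 1 and 65931 of 91311 in replicate 2. The main results used all peaks, without a filter on q. Read numbers were not in the files used, so the depth of each sample is unknown and no interval that needs it is given. The lists hold only what passed a threshold, so a gene without a peak is not shown to lack the mark, and the length of a list can follow sequencing depth.

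Positions were compared with the GENCODE M21 annotation and the RefSeq sequence of GRCm38 (patch p6), the same build as mm10. No peak ran past a chromosome end in any of the 4 lists, and all peaks lay on the autosomes and the X chromosome. Coordinates are given from 1, as a genome browser shows them. Covered shares of a chromosome were taken over its sequenced bases, leaving out unknown bases. A protein-coding gene was called marked when a peak overlapped the window 1000 bp either side of its transcription start site (TSS, the outermost annotated start) by at least 1 bp in both replicates. The covered share of a gene is the percent of bases within 5000 bp of the TSS that lay in peaks, given as the mean of the replicates with its SD. For genes with more than 1 promoter the outermost start may not be the one in use, and the annotated start of Hoxc5 lies close to that of Hoxc10. The annotated starts of Hoxd3 and Hoxd4 are also close together, and that of Hoxa3 lies between those of Hoxa6 and Hoxa7. Domains were made by merging peaks 3000 bp or less apart. Genome parts were assigned in the order promoter, exon, intron and intergenic.

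A peak was shared when it overlapped the other list by at least 1 bp. Overlap was tested against 1000 random placements of the replicate 2 intervals within their own chromosomes (bedtools 2.31.1, one-sided p). The placements did not avoid assembly gaps or unmappable sequence, which lowers the chance overlap. Gene lists and families were tested with Fisher's exact test (two-sided) against all 21911 protein-coding genes, with Benjamini-Hochberg adjustment over the 21 lists and, separately, over the 19 families. Genes are not independent replicates, and these tests describe these lists of peaks. The X chromosome was compared with the 19 autosomes by an exact permutation of which of the 20 chromosomes is set apart, two-sided, whose smallest possible p is 0.05. Intervals for shares of genes are exact Clopper-Pearson 95% intervals. Of 34 names in the list of imprinted genes, 29 genes were in the protein-coding annotation. All members of the other lists were found.

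The lists, tests, alternatives and rule for named genes were fixed before the data were examined, apart from those said below to be added or chosen later. The rule names a set of kidney and control genes chosen beforehand, up to 4 members of each list with the highest covered share, genes whose TSS lies in the 10 widest domains of the replicated list, the 5 genes in each direction with the largest difference between replicates, and genes at the 5 top-ranked peaks of each replicate. In lists with 5 or fewer marked or unmarked members, all could be named. The alternatives were −log10 q of at least 2 and at least 5, an overlap of 50%, equal numbers of top-ranked peaks, a window of 2500 bp, the gene body, at least 500 bp of the window covered, the replicated list, each replicate alone, a background matched on the promoter CpG ratio in 20 bins with 100000 draws, 1 gene kept per run of neighbours under 100000 bp apart, merging distances of 1000 and 10000 bp, and peaks per Mb. The alternatives for overlap used 100 placements.

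The interval calculations were tested on simulated data against bedtools on 20000 random intervals, where all 3 quantities matched. In simulated lists of the real sizes among the 21911 genes, the enrichment test found 95.5% of lists drawn at a marked share of 60% and called 1.5% of lists drawn at the background share. Members were drawn at random and marked independently, and only calls of enrichment were counted. These rates therefore do not describe lists of neighbouring or CpG-rich genes, or calls of depletion. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.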

Results

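H3K27me3 was profiled in 2 biological replicates of whole mouse kidney at embryonic day 16.5, a stage at which nephron progenitors, branching ureteric bud, stroma, vessels and the first differentiating nephrons are present together. The replicate 1 list held 68859 peaks covering 26.6 Mb and the replicate 2 list 91311 peaks covering 39.4 Mb, or 1.01% and 1.49% of the sequenced genome. The mean covered length was 33.0 Mb ± 9.02 (SD, n = 2). Median peak widths were 238 and 268 bp. With only peaks of −log10 q of at least 5 the covered lengths were 9.81 and 16.1 Mb. Read depth is unknown, so the difference in length is a difference between lists.

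The first question was where the mark lay in the genome and how far the replicates shared it. Promoters of protein-coding genes took 10.9% ± 1.05 of peak bases (SD, n = 2) against 1.56% of the genome, a 6.99-fold excess. Exons outside promoters held 2.18-fold their genome share, introns 0.997-fold and intergenic sequence 0.728-fold. The promoter excess was 10.8-fold with −log10 q of at least 5. Of the replicate 1 peaks, 55.8% overlapped a replicate 2 peak, against 3.28% after random placement. Of the replicate 2 peaks, 36.5% overlapped a replicate 1 peak, against 2.19%. The Jaccard index of covered bases, the shared length over the length in either list, was 0.340 against 0.00676. Each p was 0.000999, the smallest that 1000 placements can give. The placements kept neither the grouping of peaks into domains nor their preference for promoters, so these p values speak only against uniform placement. On the autosomes the Jaccard index was 0.389 and on the X chromosome 0.133.

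The overlap was highest among the strongest peaks. In the 10% of each list with the smallest p, 97.8% of replicate 1 peaks and 89.1% of replicate 2 peaks overlapped the other list, against 36.8% and 17.7% in the 10% with the largest p. The autosomal part of the strongest 10% of replicate 2 was shared at 95.2% and its X-linked part at 52.5%.

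**Figure D1:**
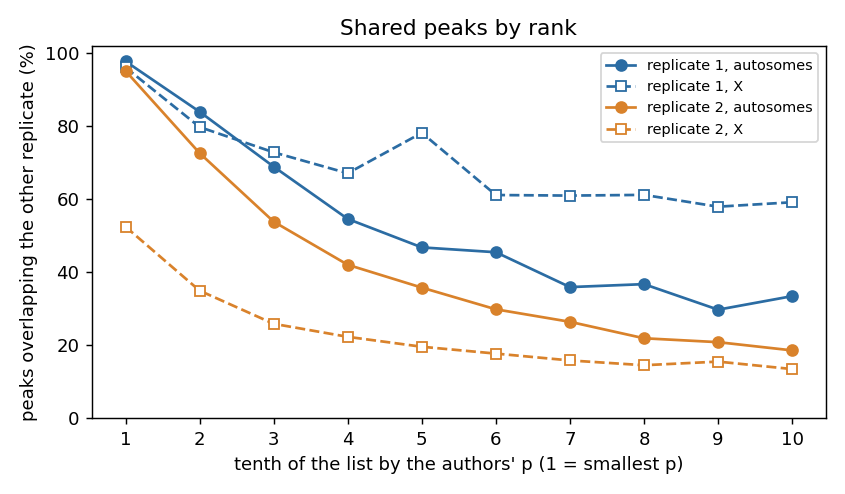
Percent of peaks that overlapped the other replicate (vertical axis) in 10 equal parts of a list ranked by the authors' p (horizontal axis), for autosomes (filled points) and X (open squares). The strongest part of the autosomal peaks was shared at 97.8% in replicate 1 and 95.2% in replicate 2, and X-linked peaks of replicate 2 lay lowest, from 52.5% to 13.5%.

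The 5 peaks with the smallest p were located in each replicate. In replicate 1 the first was inside Rbfox3, which encodes the neuronal nuclear protein NeuN (chromosome 11, 118567106 to 118571740), mostly intronic with 7.77% of its bases in exons. It was followed by peaks over the TSS of Helt (chromosome 8, 46290255 to 46297624) and over the TSSs of Chat and Slc18a3, which make and load acetylcholine (chromosome 14, 32460657 to 32467735). The next lay between genes, 7050 bp from the TSS of Skor2 (chromosome 18, 76845357 to 76849355), and the last lay 1858 bp from the TSS of the pancreatic and cerebellar regulator Ptf1a (chromosome 2, 19447521 to 19454965), over the noncoding gene 1810010K12Rik, with 30.3% of its bases in exons. In replicate 2 they lay over the TSSs of Gsx1 (chromosome 5, 147185975 to 147193575), Egr4 (chromosome 6, 85509887 to 85514526) and Neurog3 (chromosome 10, 62127122 to 62134830), inside Rbfox3 again (chromosome 11, 118567534 to 118572740), and at a ribosomal RNA locus on chromosome 17 (39843013 to 39846784). The authors' signal at the ribosomal RNA locus was 2.44, which was higher than in only 4.46% of that list's peaks, while the other 9 peaks were above 99.9% of the peaks in their lists.

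The authors' whole-series lists were set against the replicate lists. The joint list held 69810 peaks, of which 41.6% overlapped both replicates, 15.6% replicate 1 only, 36.0% replicate 2 only and 6.78% neither. The replicated list held 36161 peaks, each identical in position to a joint peak, and 78.0% of them overlapped both replicates. A further 16.4% overlapped replicate 2 only and 5.26% replicate 1 only. The share overlapping both fell to 37.9% when every list was restricted to −log10 q of at least 5.

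Among 21911 protein-coding genes, 3245 (14.8%) were marked at the promoter in both replicates, against 732 if the calls of the replicates were independent. Replicate 1 alone marked 444 genes and replicate 2 alone 1100. The number marked in both was 1446 with −log10 q of at least 5, 2043 when 500 bp had to be covered and 5060 when any overlap with the gene body counted.

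Lists of neural, endodermal and muscle regulators were examined first. All 40 neural transcription factors were marked (exact adjusted p = 1.13e-32, Fisher's exact test as in all lists below), among them Olig2, the oligodendrocyte and motor neuron factor, with a covered share of 98.8% ± 1.01, and Prdm12, with 98.8% ± 0.226. Lhx5 and Neurog1 had 98.1% ± 0.431 and 97.5% ± 3.47. All 20 regulators of endoderm, liver and pancreas were marked (exact adjusted p = 1.72e-16), led by the intestinal factor Cdx2 (98.2% ± 0.438), Neurog3 (97.2% ± 1.15), Onecut1 (96.7% ± 1.89) and Barx1 (96.0% ± 3.83). In the list of cardiac and skeletal muscle regulators 19 of 20 were marked (exact adjusted p = 1.5e-14). These included Pax7 (96.8% ± 2.85), the muscle stem cell factor, Tbx5 (94.0% ± 2.3), the heart and forelimb factor, and Tbx20 (92.3% ± 3.44). Pax3 had 92.1% ± 7.65. The exception was Myog, at 0.91% ± 1.29. All values are SD over n = 2.

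Regulators of the kidney itself were marked as well. In the list of nephron progenitor and cap mesenchyme genes 17 of 20 were marked (exact adjusted p = 2.34e-11). Only 10 were when at least 500 bp had to be covered and 6 with −log10 q of at least 5. The list still passed in both settings (exact adjusted p = 1.12e-05 and 0.00298). Lhx1 had a covered share of 81.0% ± 12.9, Six1 79.9% ± 3.47 and Fgf8 68.9% ± 19.2 (SD, n = 2). Six2, which maintains nephron progenitors (TSS on chromosome 17 at 85688274), had 74.0% ± 3.32. Wt1 (chromosome 2, 105126529) had 52.4% ± 10.8 and Pax2 (chromosome 19, 44756045) 49.5% ± 17.3. Osr1 had 48.5% ± 7.8 and the X-linked Cited1 45.5% ± 20.1, with 31.3% in replicate 1 and 59.7% in replicate 2. Sall1 had 28.8% ± 16.5 and Pax8 had 27.5% ± 8.53. Gdnf, the ligand by which the mesenchyme induces the ureteric bud, had 42.4% ± 21.5. The unmarked members were Hoxa11 (10.3% ± 6.17) and Itga8 (3.53% ± 4.99), both with a promoter peak in replicate 2 only, and Gas1, with no peak base within 5000 bp of its TSS in either replicate.

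In the ureteric bud and collecting duct list 16 of 20 were marked (exact adjusted p = 4.84e-10). Only 13 were when at least 500 bp had to be covered and 7 with −log10 q of at least 5. The list still passed in both settings (exact adjusted p = 6.75e-09 and 0.000509). Gata3 had 87.6% ± 8.56, Wnt9b 81.3% ± 4.06, Emx2 74.5% ± 7.01 and Wnt11 71.2% ± 5.56 (SD, n = 2). Ret, the receptor for Gdnf, had 51.9% ± 5.71, and Aqp2, the vasopressin-regulated water channel, 36.8% ± 0.799. Krt19, Avpr2, Foxi1 and Hoxb7 were not marked in both. Of the podocyte genes 9 of 16 were marked (exact adjusted p = 0.000377), with Nphs1 and Nphs2, which encode the slit diaphragm proteins nephrin and podocin, at 90.3% ± 7.16 and 42.8% ± 1.26. Lmx1b had 85.5% in replicate 1 and 94.5% in replicate 2, Podxl 68.0% ± 3.24 and Mafb 61.6% ± 2.84.

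Genes of the differentiated tubule were examined next. In the proximal tubule list 4 of 20 were marked, which did not pass the test (exact adjusted p = 0.612). They were Lrp2 (50.5% ± 9.73, SD, n = 2), which encodes the endocytic receptor megalin, Slc27a2 (37.9% ± 2.71), Fbp1 (24.5% ± 5.32) and Gatm (8.83% ± 6.21). No peak base lay within 5000 bp of the outermost annotated TSS of Hnf4a in either replicate. Peaks covered 1.34% of its gene body in replicate 1 and 1.84% in replicate 2, and starts further inside the gene were not examined. The phosphate transporter gene Slc34a1 had 1.10% ± 1.56. In the loop of Henle and distal tubule list 7 of 18 were marked (exact adjusted p = 0.0165). The highest members were transcription factors, Irx2 (93.7% ± 0.848), Irx1 (92.9% ± 2.26), Pou3f3 (72.4% ± 12.1) and Sim1 (61.0% ± 3.5). Umod, which encodes uromodulin, had no peak base within 5000 bp of its TSS, and the salt transporter genes Slc12a1 and Slc12a3 had 1.77% ± 2.51 and 0.890% ± 1.26, without a promoter peak. The loop and distal tubule list no longer passed with −log10 q of at least 2 (exact adjusted p = 0.0721) or 5 (exact adjusted p = 0.156). Its ratio of marked to expected genes, 2.63, was only slightly lower in both settings.

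Stroma, vessels and blood are the other cell types of the organ. In the stroma list 9 of 20 were marked (exact adjusted p = 0.0023), led by Foxd1 (74.6% ± 5.75, SD, n = 2), the factor of the stromal progenitors, Tbx18 (74.2% ± 5.64), Alx1 (72.9% ± 2.74) and Pdgfra (66.2% ± 13.7). In the endothelium list 8 of 16 were marked (exact adjusted p = 0.00203), with Flt1 at 82.7% ± 3.02, Sox17 at 75.5% ± 2.3, Erg at 67.1% ± 3.48 and Kdr, the VEGF receptor, at 50.5% ± 9.19. No peak base lay within 5000 bp of the TSS of Pecam1. In the blood and immune list 2 of 18 were marked, Tal1 (79.9% ± 4.51) and Ikzf1 (54.6% ± 2.08), and the list did not pass (exact adjusted p = 1). Its ratio of marked to expected genes, 0.750, ranged from 0.722 to 1.69 over the alternatives, and none passed.

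**Figure D2:**
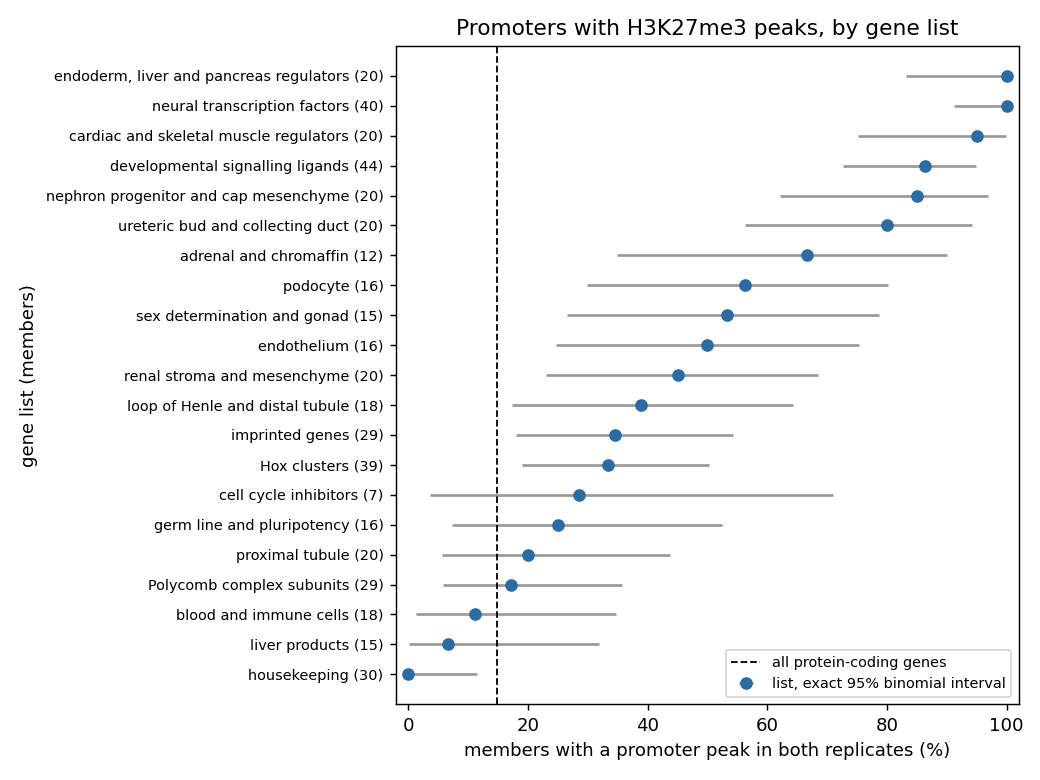
Percent of the members of each gene list with a promoter peak in both replicates (points, horizontal axis) with exact 95% binomial intervals (bars), against 14.8% of all protein-coding genes (dashed line). The lists of neural, endoderm and muscle regulators lay at 95% to 100%, the adrenal list at 66.7%, the gonad list at 53.3% and housekeeping genes at 0%.

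The adrenal gland and gonad lie beside the kidney. In the adrenal and chromaffin list 8 of 12 were marked (exact adjusted p = 0.000195), led by Gata2 (94.7% ± 4.35), Phox2b (93.1% ± 3.63), Hand2 (90.9% ± 5) and Phox2a (59.9% ± 5.37). In the list for sex determination and gonad 8 of 15 were marked (exact adjusted p = 0.00129), with Insl3 at 99.6% ± 0.559, Foxl2, the ovarian factor, at 90.2% ± 4.95, Dmrt1 at 76.3% ± 8.53 and Rspo1 at 76.3% ± 16.5. Among developmental signalling ligands 38 of 44 were marked (exact adjusted p = 7.39e-25), with Wnt10a at 94.8% ± 2.87, Wnt10b at 92.4% ± 4.36, Ihh at 85.9% ± 5.73 and Gdf7 at 85.3% ± 5.13 (SD, n = 2).

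The imprinted list had 10 of 29 marked (exact adjusted p = 0.0109), with Dio3 (89.4% ± 8.65), Ascl2 (67.2% ± 4.6), Dlk1 (66.9% ± 6.34) and Grb10 (65.4% ± 8.2) highest. Of the Polycomb subunit genes 5 of 29 were marked, which did not pass (exact adjusted p = 0.672). They were Cbx8 (72.3% ± 5.68), Pcgf5 (50.4% ± 1.1), Cbx4 (48.4% ± 1.76), Pcgf1 (35.6% ± 2.74) and Cbx2 (14.0% ± 2.87). The ratio to the expected number was 1.16 and ranged from 0.740 to 1.40 over the alternatives, and none passed. Of 7 cell cycle inhibitors Cdkn2a (84.6% ± 0.742) and Cdkn2b (77.3% ± 3.13) were marked, and the list did not pass (exact adjusted p = 0.346) except with a window of 2500 bp (exact adjusted p = 0.0413). Liver products had 1 of 15 marked, Apob (exact adjusted p = 0.749), and the ratio to the expected number, 0.450, ranged from 0 to 1.19 over the alternatives, none of which passed. The germ line and pluripotency list had 4 of 16, Utf1 (61.8% ± 12), Tdgf1 (39.1% ± 3.21), Pou5f1 (16.2% ± 5.23) and Nanog (12.6% ± 4.35), with exact adjusted p = 0.346. None of 30 housekeeping genes was marked in both replicates, Actb and Gapdh included (exact adjusted p = 0.0237, interval 0% to 11.6%). That depletion no longer passed without replicate 1 (exact adjusted p = 0.146), where Pgk1 and Reep5 were marked, or in the replicated list (exact adjusted p = 0.105). Nor did it pass with −log10 q of at least 2 (exact adjusted p = 0.0645), where still none was marked but fewer were expected.

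Whole gene families were tested in the same way. All 9 Pax, 12 LIM homeobox and 14 Nkx genes were marked (exact adjusted p = 8.06e-08, 3.46e-10 and 9.06e-12, Fisher's exact test). So were 12 of 16 Tbx (exact adjusted p = 2.34e-07), 10 of 12 Iroquois and sine oculis homeobox (exact adjusted p = 4.72e-07), 5 of 6 Gata (exact adjusted p = 0.000507), 11 of 19 Sox (exact adjusted p = 3.04e-05) and 25 of 44 Fox genes (exact adjusted p = 3.6e-10). Voltage-gated potassium channels had 34 of 39 marked (exact adjusted p = 1.38e-22) and solute carriers 84 of 371 (exact adjusted p = 9.73e-05). Olfactory receptors had 6 of 1092 marked (9 in replicate 1 and 17 in replicate 2), against 162 expected (exact adjusted p = 1.94e-66). Vomeronasal receptors had 1 of 326, against 48.3 expected (exact adjusted p = 8.46e-21). Against genes matched on promoter CpG ratio the expected numbers were 27.1 and 7.53, and the ratios of marked to expected genes were 0.221 in place of 0.0371 and 0.133 in place of 0.0207 (permutation adjusted p = 4.22e-05 and 0.00882). Krueppel-type zinc finger genes had 13 of 365 (exact adjusted p = 9.06e-12), with 15 in replicate 1 and 23 in replicate 2. Ribosomal proteins had 2 of 79 (exact adjusted p = 0.000835) and core histones 0 of 61 (exact adjusted p = 0.00013). With −log10 q of at least 5 ribosomal proteins no longer passed (0.192-fold, exact adjusted p = 0.0814). Keeping 1 gene per run of neighbours left 7 core histone genes, of which 0 were marked (exact adjusted p = 0.675). Cytochrome P450 genes (9 of 100, exact adjusted p = 0.134), keratins (7 of 49, exact adjusted p = 1), protocadherins (4 of 56, exact adjusted p = 0.138) and proteasome subunits (2 of 39, exact adjusted p = 0.133) did not pass. Protocadherins turned from 0.482-fold to 2.32-fold when the gene body was counted (exact adjusted p = 2.17e-06). That test counts each member as independent, although 1 peak marks every member whose gene body spans it. Protocadherins passed as depleted with a window of 2500 bp (exact adjusted p = 0.0203), in the replicated list (exact adjusted p = 0.0159) and against matched CpG ratios (permutation adjusted p = 0.0135). Proteasome subunits passed as depleted in 3 alternatives, with exact or permutation adjusted p from 0.0223 to 0.0444. Cytochrome P450 genes passed as depleted with the wider window (exact adjusted p = 0.0348), but were at 1.29-fold against matched CpG ratios (permutation adjusted p = 0.532). Keratins, at 0.965-fold, ranged from 0 to 1.54-fold over the alternatives, and none passed.

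Of the 39 Hox genes, which set position along the body axis, 13 were marked (exact adjusted p = 0.00857). By replicate, 14 had a promoter peak in replicate 1 and 21 in replicate 2. The highest covered shares were at Hoxc12 (96.3% ± 2.74), Hoxb13 (94.9% ± 2.21), Hoxc13 (94.1% ± 2.84) and Hoxd13 (87.2% ± 1.1), the posterior ends of their clusters (SD, n = 2). Against a background matched on promoter CpG ratio the list no longer passed (permutation adjusted p = 0.0792).

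**Figure D3:**
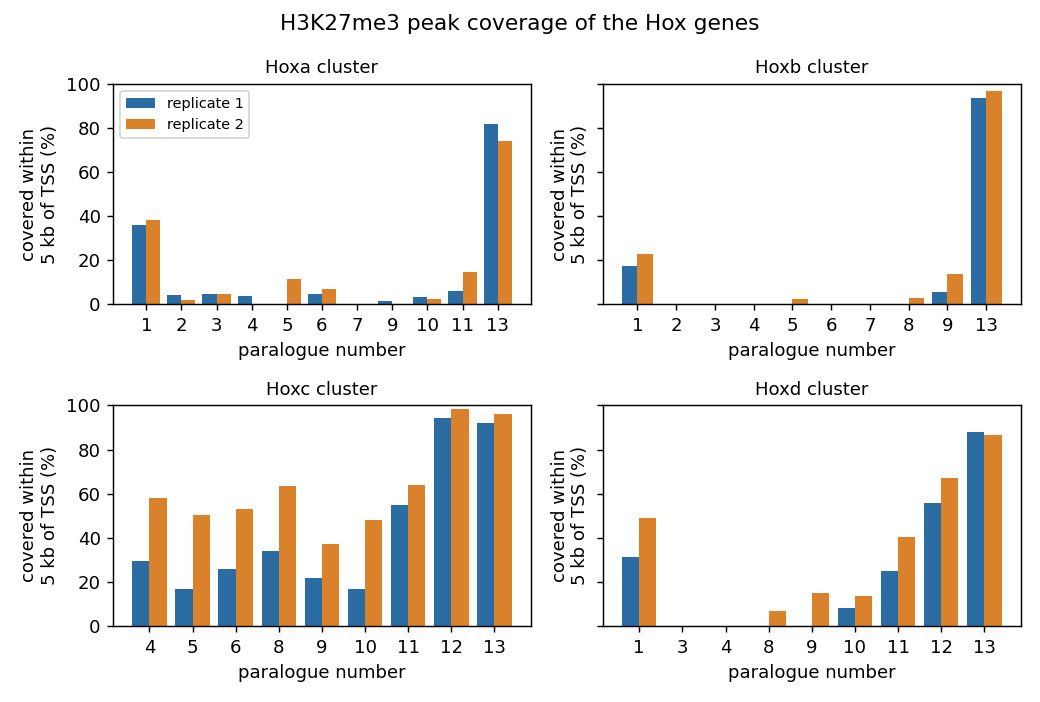
Percent of bases within 5000 bp of the TSS covered by peaks (vertical axis) for each Hox gene in order of paralogue number (horizontal axis), by cluster and replicate (bars). The bars were highest at Hoxc12, Hoxb13, Hoxc13 and Hoxd13, between 86.4% and 98.3%, all genes of the posterior ends of their clusters.

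Neighbouring peaks were merged into wide domains. In the replicated list the widest was 105 kb long over Cdh22, a cadherin gene (chromosome 2, 165162424 to 165267577), followed by 103 kb over Pax3 (chromosome 1, 78118938 to 78222046) and 88.2 kb over the TSS of Dmbx1 (chromosome 4, 115895598 to 115983771). The TSSs of Barhl1 (80.6 kb), Nfix (79.8 kb), Zic4 and Zic1 (78.6 kb) and Dmrt3 (68.0 kb) lay in others of the 10 widest. The other 3 held no protein-coding TSS, among them 1 of 74.3 kb inside Prdm16 and 1 of 71.9 kb inside Iqsec2 on the X chromosome. The 10 widest domains averaged 81.3 kb in replicate 1 and 152 kb in replicate 2, whose widest, 251 kb on the X chromosome, held the TSS of Pja1. The means were 261 and 640 kb when peaks up to 10000 bp apart were merged. Without the X chromosome, an alternative chosen after seeing the data, the mean of replicate 2 was 105 kb.

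The X chromosome was the point at which the replicates differed most. Peaks covered 1.44% of it in replicate 1 and 5.02% in replicate 2, against autosome means of 1.02% and 1.31%. The ratio of X to autosomes was 1.41 in replicate 1 (exact p = 0.15) and 3.83 in replicate 2 (exact p = 0.05, the smallest that 20 chromosomes allow). The ratio of the mean covered shares was 2.78, which rests on replicate 2. With only peaks of −log10 q of at least 5 the ratio was 0.176 in replicate 1 and 1.75 in replicate 2. From replicate 1 to replicate 2 the covered length was 3.49 times as large on the X chromosome and 1.28 times as large on the mean autosome. The range over the 19 autosomes was 1.18 to 1.35 (exact p = 0.05). This ratio between replicates was added to the planned measures, and its p ranks chromosomes within a single pair of samples, without measuring variation between replicates. No list held a peak on the Y chromosome.

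**Figure D4:**
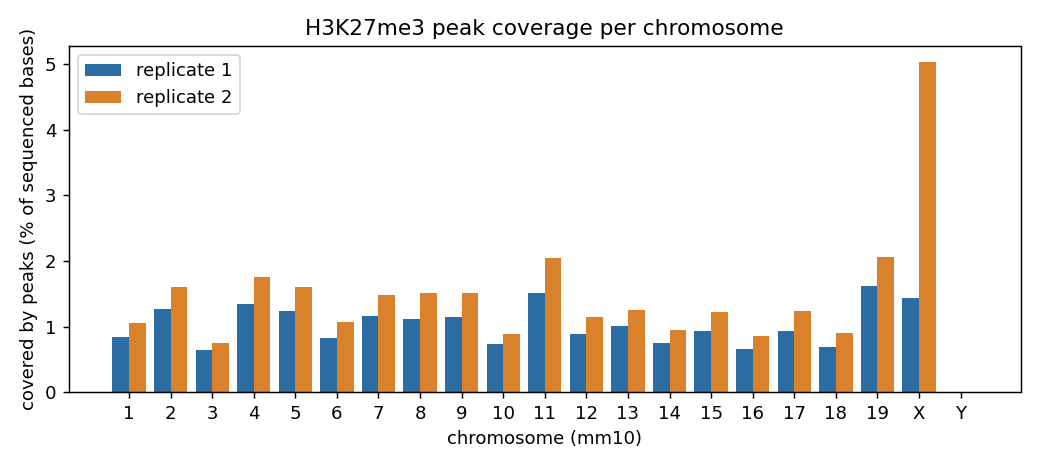
Percent of the sequenced bases of each chromosome covered by peaks (vertical axis) in replicate 1 and replicate 2 (bars). The X chromosome had 1.44% and 5.02%, and the autosomes lay between 0.644% and 2.06%.

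On the X chromosome 215 of 948 protein-coding genes were marked in both replicates, 227 in replicate 1 and 408 in replicate 2. The covered share was at least 20 percentage points higher in replicate 2 at 247 genes, of which 129 were X-linked, and at least that much lower at 0 genes. The largest gains were at the X-linked genes Nhsl2 (from 16.7% to 64.7%), Tspyl2 (from 22.5% to 69.7%), Frmpd3 (from 26.8% to 71.8%), Slc16a2, a thyroid hormone transporter (from 19.4% to 63.8%), and Reps2 (from 8.79% to 51.8%). The largest differences the other way were autosomal, at Myf6, a muscle regulator (35.7% in replicate 1 and 17.9% in replicate 2), Wif1 (58.8% and 42.4%), Tchh (32.4% and 16.1%), Hecw2 (27.1% and 11.7%) and Kcnd3 (57.4% and 43.3%). With 1 value per replicate these differences have no test.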

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

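Depth, which is unknown, limits every count of peaks and genes here, and the setting without the X chromosome was chosen after seeing the data. Overlap of the replicates stayed above random placement in each alternative (permutation p = 0.0099, the smallest for 100 placements). Jaccard indices, not computed for the overlap of 50%, ranged from 0.360 to 0.483, against 0.340 in the main setting. The share of replicate 1 peaks found in replicate 2, 55.8% in the main setting, ranged from 47.2% to 82.0%. That of replicate 2 peaks found in replicate 1, 36.5% in the main setting, ranged from 25.1% to 42.3%, with the lowest value at an overlap of 50%. Of all alternative values 440 kept their direction and side of the threshold or, without a test, stayed within the spread or, for gene counts, within a set fold. The spread between the replicates is wide, so 18.0 Mb in place of 26.6 Mb covered in replicate 1 counted as kept. Another 27 values moved, 19 turned direction, 8 gained a call and 10 lost one. The cause was not tested for the changes below, except that stricter peaks and fewer genes leave less to cover and to test.

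With −log10 q of at least 2 the joint and replicated lists overlapped both replicates at 32.4% and 47.5%, promoters, exons and intergenic sequence were at 8.21, 2.45 and 0.676-fold, the loop and distal tubule list at 2.37-fold (exact adjusted p = 0.0721) and housekeeping genes at 0 (exact adjusted p = 0.0645). With −log10 q of at least 5 the covered lengths were 9.81 and 16.1 Mb, those overlaps 37.2% and 37.9%, promoters, exons, introns and intergenic sequence 10.8, 3.11, 0.956 and 0.571-fold, marked genes 1446, the widest domains of replicate 2 on average 62.9 kb, the loop list 2.53-fold (exact adjusted p = 0.156), housekeeping genes 0 (exact adjusted p = 0.343) and ribosomal proteins 0.192-fold (exact adjusted p = 0.0814). With 50% of the peak covered the joint and replicated shares were 30.6% and 59.1%. Without the X chromosome they were 44.5% and 83.0%, promoters, introns and intergenic sequence were at 7.78, 0.979 and 0.707-fold, and proteasome genes at 0.182-fold (exact adjusted p = 0.0421). The promoter, intron and intergenic folds there set peaks off the X chromosome against genome shares that still included it.

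Counting the gene body gave 5060 marked genes and turned protocadherins from 0.482-fold to 2.32-fold (exact adjusted p = 2.17e-06). In that setting 1 peak can count for several genes whose bodies overlap. Requiring 500 bp gave 2043 genes and left housekeeping genes at 0 (exact adjusted p = 0.152). A window of 2500 bp put cell cycle inhibitors at 2.91-fold (exact adjusted p = 0.0413), cytochrome P450 genes at 0.559-fold (exact adjusted p = 0.0348) and protocadherins at 0.363-fold (exact adjusted p = 0.0203). In the replicated list housekeeping genes were at 0.22-fold (exact adjusted p = 0.105) and protocadherins at 0.236-fold (exact adjusted p = 0.0159). Matching on CpG ratio put Hox genes at 1.7-fold (permutation adjusted p = 0.0792), protocadherins at 0.353-fold (permutation adjusted p = 0.0135) and proteasome genes at 0.262-fold (permutation adjusted p = 0.0223). With 1 gene per run of neighbours proteasome genes were at 0.182-fold (exact adjusted p = 0.0444) and core histones at 0 (exact adjusted p = 0.675). Leaving out a replicate gave housekeeping genes 0 to 0.336-fold (exact adjusted p = 0.146 without replicate 1) and the X to autosome ratio 1.41 to 3.83. Merging at 1000 bp gave widest domains of 60.3 kb in replicate 2, and at 10000 bp 261 and 640 kb. Over the 11 alternatives of each result, adjusted p values by exact or permutation tests ranged from 6.49e-06 to 0.0792 for Hox genes, 0.007 to 0.156 for the loop list, 0.00619 to 0.343 for housekeeping genes, 0.0413 to 1 for cell cycle inhibitors, 0.0348 to 1 for cytochrome P450 genes, 1.23e-06 to 0.0814 for ribosomal proteins, 2.17e-06 to 1 for protocadherins, 3.44e-07 to 0.675 for core histones and 0.0223 to 0.545 for proteasome genes. Direction turned without passing in 18 further values. Blood and immune genes, at 0.750-fold, were at 1.68-fold with −log10 q of at least 5, 1.69-fold with the 2500 bp window, 1.19-fold with 500 bp covered, 1.16-fold with matched CpG ratios and 0.990 to 1.12-fold without a replicate, where only the value without replicate 1 turned. Liver products, at 0.450-fold, were at 1.15-fold with the gene body and 1.01 to 1.19-fold without a replicate. Polycomb subunits, at 1.16-fold, were at 0.740-fold with 500 bp covered and 0.779-fold with 1 gene per run of neighbours. Cytochrome P450 genes, at 0.608-fold, were at 1.29-fold with matched CpG ratios (permutation adjusted p = 0.532) and 1.29-fold with 1 gene per run of neighbours (exact adjusted p = 0.463). Keratins, at 0.965-fold, were at 1.14-fold with the 2500 bp window, 1.33-fold with the gene body, 1.08-fold in the replicated list, 1.10-fold with matched CpG ratios and 1.21 to 1.54-fold without a replicate. No paired analysis was possible because there was a single group.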

Other observations

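Across the 39 Hox genes, the mean covered share was highest in paralogue groups 11 to 13, a grouping chosen after seeing the values and so given without a test. Their 9 genes averaged 68.2% ± 30.4 (SD over genes), with 8 of them marked in both replicates. Group 11 was lower, with Hoxa11, Hoxd11 and Hoxc11 at 10.3%, 32.6% and 59.4%, while groups 12 and 13 ranged from 61.4% to 96.3%. HoxC genes of groups 4 to 10, at 29.5% to 48.9%, overlapped group 11. The 25 genes of groups 3 to 10 averaged 11.4% ± 15.9 (7.10% in replicate 1, 15.7% in replicate 2), with 2 marked in both replicates. The 5 genes of groups 1 and 2 averaged 20.2% ± 18.6, with 3 marked. At Hoxa3, Hoxc5, Hoxd3 and Hoxd4 the window at the outermost start may not lie at the promoter in use. HoxC genes averaged 43.0% in replicate 1 and 63.2% in replicate 2, while HoxA genes averaged 13.3% and 14.1%, HoxB genes 11.7% and 13.9% and HoxD genes 23.1% and 31.0%. Genes of 1 cluster are neighbours and not independent.

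Of the tests below, that of equal numbers of top-ranked peaks on the X chromosome, both comparisons of the covered share of kidney genes and the count of reference copies at the ribosomal RNA locus were chosen only after the result was seen, while matching on CpG ratio was planned and only its use as a test of an explanation came after. The first pattern is the X chromosome, covered 3.49 times as much in replicate 2 as in replicate 1. The length of the list alone does not account for it. Among equal numbers of top-ranked peaks (34429 in each) the X share was 7.9% in replicate 1 and 31.6% in replicate 2, a ratio of 4.00. Equal numbers of peaks do not equalise sequencing depth, which is unknown, so a difference in depth stays open. A ratio above that of the highest whole autosome, 1.35, was found in 94.1% of the 10-Mb bins of the X chromosome (16 of 17). A raised ratio was therefore not confined to a few bins. The count does not measure where the excess lies, because bins count alike whatever their covered length. The bin from 160000001 to 170000000 rose from 515683 to 1844544 bp, and that from 120000001 to 130000000 from 1299 to 4524 bp. Autosomes were not divided into bins. A larger share of cells with an inactive X chromosome in replicate 2, as a pool with more female embryos would give, may account for it and stays open, and the sex ratio of the pools was not given in the sources used here. Gene bodies of 5 genes that escape X inactivation (Kdm5c, Kdm6a, Ddx3x, Eif2s3x and Pbdc1) gained 0.246 percentage points. The gain was 8.45 for 264 other X-linked genes with a promoter CpG ratio of at least 0.5. The difference of −8.20 did not pass with so few genes, all at 0 in replicate 1 (permutation p = 0.0732). The 264 genes were not matched on expression. Gene bodies of the X-linked housekeeping genes Hprt and Pgk1 also rose little, from 0% to 1.28% and from 2.11% to 6.53%. The contrast therefore cannot tell escape from wide expression.

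The second pattern is the ribosomal RNA locus on chromosome 17, among the 5 top-ranked peaks of replicate 2 at a signal of 2.44 and also overlapped by a peak of replicate 1. A candidate explanation is that reads from many ribosomal gene copies were placed on 1 locus. The planned test came out against it, since 5.14% of the peak's bases were soft-masked repeat sequence, under the bound of 10% set beforehand and below the 11.5% median of the 100 top-ranked peaks. A check added after that result showed why the bound was wrong, because each of 10 stretches of 50 bp from the peak occurred once in the reference, so masking could not count copies that are missing from it. Copies and a true domain cannot be told apart here for want of a control sample, and no biological explanation was tested.

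The third pattern is the marking of developmental regulators. The promoter CpG ratio alone does not account for it, since 13 of the 14 enriched lists stayed enriched against background genes matched on it. The Hox list was the exception. Some lists share members such as Pax3 and Pax7, so these are not 14 separate tests. GC content and the length of CpG-rich sequence were not matched, so CpG richness in a wider sense is not excluded. A hypothesis is that kidney regulators carry the mark in only part of the cells of this mixed tissue, which the values leave open. The 40 nephron progenitor and ureteric bud genes had a mean covered share of 35.9% against 87.5% for the 40 neural factors (difference −51.7 percentage points), a contrast already seen, which sets lists that also hold effector genes such as Aqp2 against transcription factors alone. Against 26 adrenal and gonad genes, lists that mix both kinds as well, a mean of 37.5% gave a difference of −1.64 percentage points (permutation p = 0.835), so the kind of gene and the share of cells cannot be told apart.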
